A study of Mus musculus with 48 samples.

How the data were processed

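Gene expression was measured on Affymetrix Mouse Exon 1.0 ST arrays, per the labels, in mouse embryonic stem cells of 3 lines that differ in their sex chromosomes. The XX and XO cells carry the name Pgk12.1, and the XY cells are E14. All were moved from medium with inhibitors of Gsk3 and Mek1 and the cytokine LIF to fibronectin with Activin A and basic Fgf. That change takes naive embryonic stem cells towards epiblast stem cells, which resemble the later epiblast. Samples ran from 0 to 84 h. The table holds 48 arrays, of which 18 are XX, 19 XO and 10 XY, and 1 is a commercial mouse reference RNA. The reference array was grouped by its source name, because its description names another sample, and it was left out of every comparison.

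The values are log2 expression values per Ensembl gene, made by the authors with RMA and the affy package, per the submitters' processing notes. RMA corrects background, equalises arrays by quantiles and summarises probes. Its version, the probe annotation and the genome build are not given in the sources used here. The table has 22745 genes and every value column was matched to 1 sample by its title. Arrays have no read depth, so the number of arrays limits the precision. Replicate letters A and B exist for XX, XO and XY at 0 h and for XX and XO at 36 h, which makes 10 arrays of 5 conditions. The other 37 conditions have 1 array each. The labels do not say that A and B were separate cultures, so p-values measure the spread between these arrays, part of which may be technical. The standard deviation of A minus B over genes was 0.32 to 0.39 log2 units.

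The files used here do not pair the Ensembl gene identifiers with symbols or chromosomes. The gene table at hand, of assembly GRCm38.p6, has 49997 genes but its Ensembl column is empty, so 0 identifiers could be matched. The 29 gene lists, the comparisons of X-linked genes, the naive and primed scores, the restriction to autosomal genes and the rule for named genes, all chosen before the data were examined, therefore had to be left out. In their place, genes were grouped by their change in the XY line, a choice made after seeing the data. At most 2 identifiers per direction are printed for 2 comparisons, without names. At 0 h they are the genes with the largest XX minus XO difference among those past the threshold with the same sign in all 4 pairs of arrays. For the courses they are the genes with the largest XO change among those past the threshold in all 3 lines.

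Tests used R 4.3.3 and limma 3.58.1 (lmFit and eBayes, two-sided, Benjamini-Hochberg over 22745 genes, adjusted p under 0.05). Comparisons at 0 h and 36 h used the 10 duplicated arrays with 1 mean per condition, which leaves 5 residual degrees of freedom and a prior of 3.87. The contrasts were XX, XO and XY against each other at 0 h, XX against XO at 36 h, the change from 0 to 36 h in XX and in XO, and the difference of those changes. Time courses were natural cubic splines with 4 degrees of freedom per line (splines 4.3.3, knots at 17, 36 and 56 h) over 47 arrays, with 32 residual degrees of freedom. The F test of the spline terms called a course, and the fitted 84 h minus 0 h value gave its direction. For the XX by XO interaction, the direction was that of the largest fitted difference in change. A line's average difference was taken over the 16 times that XX and XO share. Arrays of 1 course are not known to be independent cultures. Numbers expected for independent lists treat all genes as equally likely to be called. Tests from 1 fit share the spread of each gene, so part of an excess of shared genes can come from that.

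Genes called in the XY course that changed by at least 1 log2 unit formed an XY-rising and an XY-falling class. Each was split by the time at which XY reached 50% of its 84 h change (before 24 h, 24 to 48 h, from 48 h). XY transient classes held called genes that ended within 0.5 log2 units of their start and moved by at least 1 in between. A class score was the mean change from the 0 h arrays of the same line. XX minus XO scores at the 15 shared times after 0 h entered an exact two-sided sign-flip permutation test, adjusted over the 10 classes. The 15 differences share the 4 arrays at 0 h and follow each other in time, so they are not independent and the p-values are likely too small. For position, each XX and XO array was placed at the hour of the fitted XY course nearest to it in Euclidean distance, on a 1 h grid, over the same genes centred on 0 h. Correlations with time used permutation tests with 100000 resamples.

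The fits across genes were tested on simulated data with 22745 genes, 100 of them changed per size. For XX against XO at 0 h, 0% of changes of 0.5 log2 units and 30% of changes of 1 were recovered. For the XX course these shares were 8% and 65%, for the interaction 1% and 24%, and for the average difference 88% and 100%. False calls numbered 3, 6, 1 and 7. A delay of 12 h put into simulated arrays was returned as -11.8 h, over 4574 genes and the times from 12 h on. Those arrays followed the fitted XY course apart from noise, so accuracy in hours was not checked for courses of another shape. The sign-flip test gave p under 0.05 in 6% of 200 simulated sets of independent values without a difference. The differences tested here share 0 h arrays and follow each other in time, so this check does not cover them. Alternatives covered scaling, a filter on low genes, the variance prior, array weights, a size threshold, the source of the spread, the spline, the distance measure, the replicate block and each array left out. Centring of arrays on their medians and quantile normalization of the gene values were chosen after seeing the data. Plots were drawn with matplotlib 3.10.9 and pandas 2.3.3.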

Results

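The data followed the passage of XX, XO and XY mouse embryonic stem cells towards epiblast stem cells over 84 h. XX cells were sampled at 16 times, XO cells at 17 and XY cells at 9. Array medians lay between 6.80 and 7.10 log2 units. At 0 h they were 6.98 and 6.98 in XX, 6.84 and 6.91 in XO, and 6.85 and 6.80 in XY. Replicate arrays A and B correlated at 0.983 to 0.988 across genes, which are not independent replicates. The narrowest interquartile ranges were those of XO at 60 h (2.77 log2 units), XO at 52 h (2.81), XY at 32 h (2.86), XO at 12 h (2.89) and XO at 56 h (2.90). Among cell arrays, the XY array at 84 h had the lowest mean correlation with the other cell arrays (0.901).

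The first comparison asked how undifferentiated XX cells, with a pair of X chromosomes, differ from XO cells, with 1. At 0 h, 1713 genes were higher and 369 lower in XX than in XO, so 2082 of 22745 genes passed (limma, adjusted p under 0.05). Of these, 745 were higher and 151 lower by at least 1 log2 unit. The identifier ENSMUSG00000035299 had the largest measured difference among called genes, with 12.33 ± 0.095 in XX, 5.55 ± 0.21 in XO and 13.11 ± 0.087 in XY (SD, n = 2). It was higher in XX by 6.77 (SE 0.21, limma adjusted p = 3.26e-06) and stayed between 4.74 and 6.68 in all XO arrays, against 12.11 to 13.18 in all XX and XY arrays. Background levels were not used here, and the XO values lie below the array medians, so this and other differences from values this low can understate the true ones. ENSMUSG00000030208 was higher in XX by 5.64 (SE 0.34, limma adjusted p = 1.30e-04) and still higher at 36 h by 3.91. ENSMUSG00000019989 and ENSMUSG00000028487 were lower in XX, with XX minus XO values of -2.75 (SE 0.37, limma adjusted p = 0.00297) and -2.58 (SE 0.16, limma adjusted p = 1.39e-04). Their 36 h values, -0.67 (limma adjusted p = 0.340) and -0.38 (limma adjusted p = 0.202), did not pass. Centring arrays on their medians took the all-gene median difference from 0.058 to -0.051, so it reversed the offset. It gave 1153 genes higher and 553 lower, and quantile normalization gave 1081 and 620. Leaving out 1 array lowered the count to 1308 without XX A, 1365 without XX B, 818 without XO A and 689 without XO B, with at least 81.2% higher in XX each time.

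XX cells also differed from XY cells, which have 1 X chromosome as XO cells do but come from another line. At 0 h, 2001 genes were higher and 827 lower in XX than in XY (limma, 2828 genes). Centring took the all-gene median difference from 0.088 to -0.071, so it reversed the offset, and gave 1247 higher and 1481 lower. Quantile normalization gave 1394 and 1260, still with more genes higher. The direction of this excess thus rests on the scaling, and it turned with centring alone. Between XO and XY, 972 genes were higher and 1234 lower in XO (2206 genes). A set of 870 genes was higher in XX than in both other lines, where independent lists would share 151, and 133 genes were lower than in both, against 13.4. These comparisons use the same XX arrays. Simulated unchanged lines sharing them gave 0 and 0 such genes, and a correlation of the differences across genes of 0.499 beside the observed 0.525. With no line difference put in, hardly any gene could be called, so this overlap bears on array noise alone. The observed covariance was 0.13 and the simulated 0.032. With XX replicates divided so that no array was shared, the correlation was 0.278 and 0.313. Both differences contain the XX level, so lines that each differ would also share genes and correlate. These values therefore do not show that XX stands apart more than XO or XY. The XX against XY count fell to 1673 without XX B, 1319 without XY A and 1343 without XY B. The XO against XY count was 744 without XO A, 535 without XO B, 718 without XY A and 758 without XY B.

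To follow the 0 h differences through the course without reusing the arrays that chose them, genes were chosen on replicate A and measured on replicate B, a step added after seeing the data. The 780 genes at least 0.5 log2 units higher in XX A than in XO A and XY A at 0 h, with no call in the XY course, had a median XX minus XO difference of 0.44 on replicate B, relative to all genes. Of these genes 75.9% were higher in XX on replicate B, against 54.0% of all genes. The median was 0.29 over 6 to 24 h and 0.14 over 66 to 84 h. It fell with time over the 16 shared times (Pearson r = -0.840, permutation p = 6e-05, adjusted over 2 sets 1.2e-04; Spearman rho = -0.774, permutation p = 7.7e-04, adjusted 0.00154), and r was -0.722 without the 2 times farthest from the median time. The 273 genes chosen as lower in XX had a median of -0.28 at 0 h and 0.0032 over 66 to 84 h (r = 0.647, permutation p = 0.00539, adjusted 0.00539; rho = 0.597, permutation p = 0.0164, adjusted 0.0164). Without the 2 farthest times their r was 0.365, so that relation rests largely on those times. Both sets were chosen at 0 h, so a smaller difference at other times can come from that choice alone.

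**Figure D1:**
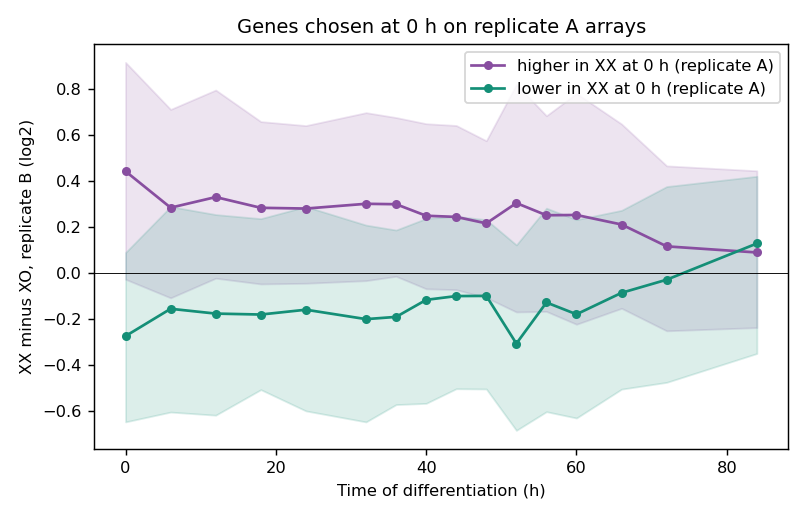
Median XX minus XO difference on replicate B arrays (vertical axis, log2, relative to the median of all genes) against time of differentiation in hours, for genes chosen at 0 h on replicate A arrays; points are medians over genes and shaded bands span the quartiles. The higher set moves from 0.44 at 0 h to a mean of 0.14 over 66 to 84 h, and the lower set from -0.28 to 0.0032.

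At 36 h, on the way between both states, XX and XO cells still differed. Here 1277 genes were higher and 764 lower in XX (limma, 2041 genes). Of the genes called at both times, 630 were higher and 110 lower in XX at 0 h and 36 h, where independent lists would share 96.2 and 12.4, and 33 had opposite directions. Part of this excess can come from the spread per gene that both tests share. The differences at both times correlated at 0.415 across genes. Centring gave 1022 higher and 1037 lower at 36 h and quantile normalization 1165 and 1009, so the excess of higher genes in the whole list depends on the scaling. Among all genes, whether called or not, 741 were higher and 367 lower by at least 1 log2 unit, and 683 and 406 after centring. The count was 935 without XX A, 801 without XX B, 867 without XO A and 1065 without XO B.

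The change from 0 to 36 h asked how far each line had moved. In XX cells 1505 genes rose and 1534 fell (limma, 3039 genes), or 1285 and 1910 after centring and 1405 and 1634 after quantile normalization. In XO cells 2708 rose and 1588 fell (4296 genes), or 2015 and 2099 after centring and 2146 and 2188 after quantile normalization. Both lines changed 1817 genes, where independent lists would share 574, and 1791 of these moved in the same direction. The test of the difference between the changes called 376 genes, of which 151 had a higher and 225 a lower XX minus XO value. Among them 158 moved in the same direction by less in XX, 57 by more in XX, and 161 had opposite signs in both lines. The XX count was 1838 without XX 36 h A, 1612 without XX 36 h B and 1791 without XX 0 h B. Its near-even split turned without XX 36 h B (871 rose, 741 fell) and without XX 0 h A (1474 and 1433). The XO count was 2519 and 2217 without XO 0 h A and B, and 2797 and 2345 without XO 36 h A and B. The 376 genes became 57 without either XX 36 h array, 149 without XX 0 h B, 77 and 64 without XO 0 h A and B, and 79 and 100 without XO 36 h A and B.

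Over the whole course, each line changed a large share of its genes. In XX cells 4168 genes ended higher and 3577 lower (limma F test, 7745 genes), in XO cells 8180 and 4086 (12266 genes), and in XY cells 5644 and 5776 (11420 genes). By at least 1 log2 unit, 2037, 3286 and 3956 genes changed in XX, XO and XY. XY has 10 arrays and XX and XO have 18 and 19, so these counts differ in power too. A total of 5323 genes changed in all 3 lines, of which 2355 ended higher and 1455 lower in each. XX and XO shared 6592 genes (independent lists, 4177), with the same direction in 75.7%. XO and XY shared 8398 (6159), with 78.0%, and XX and XY 5835 (3889), with 81.0%. The tests of the 3 lines share 1 spread per gene, so part of the excess in shared genes can come from that. The fitted change correlated across genes at 0.693 between XO and XY, at 0.575 between XX and XO and at 0.565 between XX and XY. Centring took the all-gene median change from 0.12 to -0.12 in XO and from 0.032 to -0.068 in XX, which reversed its sign. It gave 6029 higher and 6276 lower genes in XO and 3523 and 4588 in XX, and quantile normalization gave 6184 and 5745 in XO and 4151 and 4051 in XX. The XX split also turned without the XX 84 h array (3518 higher and 3820 lower), and the XY split without the XY 84 h array (4631 and 4194).

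Among genes that changed in all 3 lines, ENSMUSG00000000805 rose from 6.12 ± 0.34 to 12.50 in XX, from 5.41 ± 0.15 to 12.63 in XO and from 5.64 ± 0.48 to 12.53 in XY between 0 h (SD, n = 2) and 84 h (1 array). Its fitted changes were 6.51 (SE 0.34), 7.66 (SE 0.34) and 6.86 (SE 0.35), with limma adjusted p of at most 2.85e-21. ENSMUSG00000022425 rose from 4.03 to 5.20 ± 0.25 at 36 h in XX and from 3.96 to 9.52 ± 0.23 in XO (SD, n = 2). At 84 h it stood at 8.10 in XX, 10.48 in XO and 10.64 in XY, and its courses in XX and XO differed (limma interaction adjusted p = 2.01e-06). ENSMUSG00000075602 fell in the 3 lines, with fitted changes of -7.20 (SE 0.49) in XX, -6.75 (SE 0.49) in XO and -5.91 (SE 0.51) in XY. ENSMUSG00000067299 fell from 11.80 to 8.12 ± 0.048 at 36 h and 5.63 at 84 h in XX. In XO it fell from 11.29 to 6.26 ± 0.42 and 4.65, and in XY, where it started at 5.93, by a fitted change of -1.64 (SE 0.35).

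**Figure D2:**
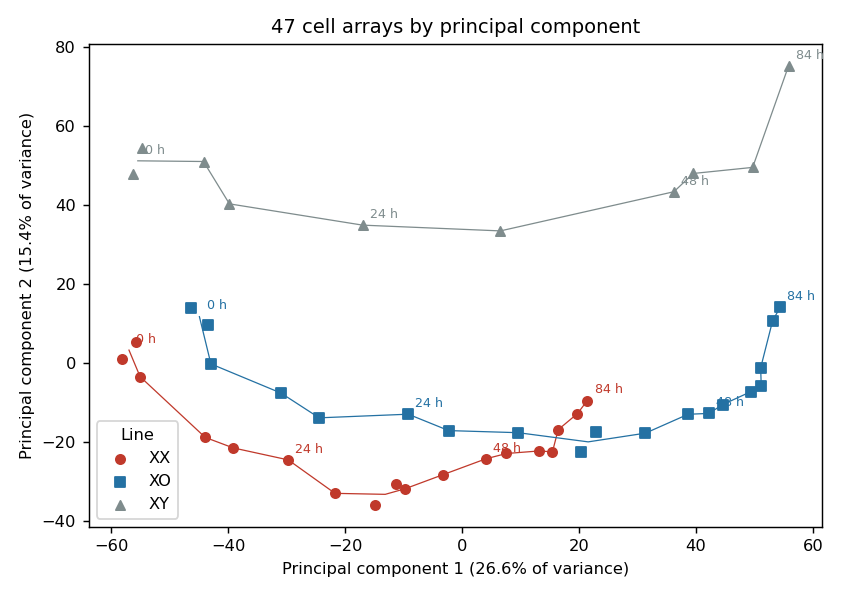
Positions of the 47 cell arrays on the first principal component (horizontal axis, 26.6% of the variance) and the second (vertical axis, 15.4%); each point is an array, lines join the mean of each time within a line, and times are marked at 0, 24, 48 and 84 h. On the first component the 84 h arrays lie at 21.4 in XX, 54.4 in XO and 55.8 in XY.

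The next comparison asked whether XX cells made the same changes as XO cells to the same extent, on genes chosen in the XY line, which is in neither arm. Smaller or later changes in XX and XO than in XY can come from that choice alone. The mean change of the 1952 XY-rising genes was lower in XX than in XO at 15 of 15 times. The mean XX minus XO difference in change was -0.27 ± 0.16 log2 units (SD over 15 times; exact sign-flip permutation test, p = 6.10e-05, the smallest possible; adjusted over 10 classes 2.03e-04). At 36 h their mean change was 0.49 in XX and 0.75 in XO, and at 84 h it was 0.95 in XX, 1.45 in XO and 1.82 in XY. Of these genes 1276 were called rising in XX and 1637 in XO. XO and XY reached 50% of the XY 84 h change after 42.7 and 41.6 h, and XX after 80.9 h, a time that rests on the XX 84 h array. These are first crossings, and XO fell back from 0.97 at 48 h to 0.79 at 52 h. The mark itself rests on the XY 84 h array, at 1.82 against 1.54 in XY at 72 h. A lower mark would bring the XX time forward. As a difference in level and not in change, the XX minus XO value was -0.087 (exact sign-flip permutation test, p = 0.0576), which did not pass.

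By timing in XY, the 638 genes that rose before 24 h reached that 50% mark after 35.0 h in XX, 18.3 h in XO and 10.1 h in XY. The 588 genes that rose between 24 and 48 h reached it after 57.2, 40.0 and 36.4 h. The 726 genes that rose from 48 h reached it after 67.1 h in XO and 65.3 h in XY and did not reach it in XX, where their mean change at 84 h was 0.62 against 1.26 in XO. The marks of these groups also rest on the XY 84 h array. The XX minus XO differences of these 3 groups were -0.20, -0.33 and -0.29 (exact sign-flip permutation test, adjusted p = 0.0117, 2.03e-04 and 2.03e-04). XX was lower at all 15 times in the later groups, but higher at 4 of 15 times in the earliest. Centring reduced the size of the earliest group's difference to -0.12 (same permutation test, adjusted p = 0.0342).

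The 2004 XY-falling genes gave a less clear result for the change from 0 h. Their XX minus XO difference in change was 0.094 ± 0.16 (SD over 15 times), above 0 at 11 of 15 times (exact sign-flip permutation test, p = 0.0405, adjusted 0.0507), which did not pass after adjustment. With centred arrays the difference was 0.17 (p = 9.77e-04, adjusted 0.00173, same permutation test) and with quantile normalization 0.20 (p = 4.27e-04, adjusted 8.14e-04, same permutation test). As a difference in level and not in change, the XX minus XO value of the XY-falling genes was 0.25 (exact sign-flip permutation test, p = 1.22e-04). The level of the XY-rising genes over those times did not pass, so which class is clearer differs between change and level. The tests of change and level differ both in the 0 h baseline and in whether 0 h is among the times. At 84 h the mean change was -0.63 in XX, -0.79 in XO and -1.93 in XY, and 966 of these genes were called falling in XX and 1191 in XO. For the 734 genes that fell between 24 and 48 h in XY, of which 460 were called falling in XX and 534 in XO, the XX minus XO difference was 0.20 (exact sign-flip permutation test, adjusted p = 0.0190), or 0.27 after centring and 0.32 after quantile normalization. The 558 genes that fell before 24 h gave a value that did not pass (-0.048, exact sign-flip permutation test, adjusted p = 0.10). Their value was 0.027 after centring (same permutation test, adjusted p = 0.188) and 0.059 after quantile normalization (same permutation test, adjusted p = 0.0113), so its sign and its call depend on the scaling. For the 712 genes that fell from 48 h in XY, the XX minus XO difference was 0.10 (exact sign-flip permutation test, adjusted p = 0.0393), or 0.18 after centring and 0.20 after quantile normalization. Their choice rests largely on the XY 84 h array, at -1.96 in XY against -0.41 in XO and -0.10 in XX. Of these genes 147 were called falling and 58 rising in XX, and 283 falling and 89 rising in XO. Without that array the classes held 2094 rising and 1625 falling genes, of which 1275 and 993 were in the classes above.

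**Figure D3:**
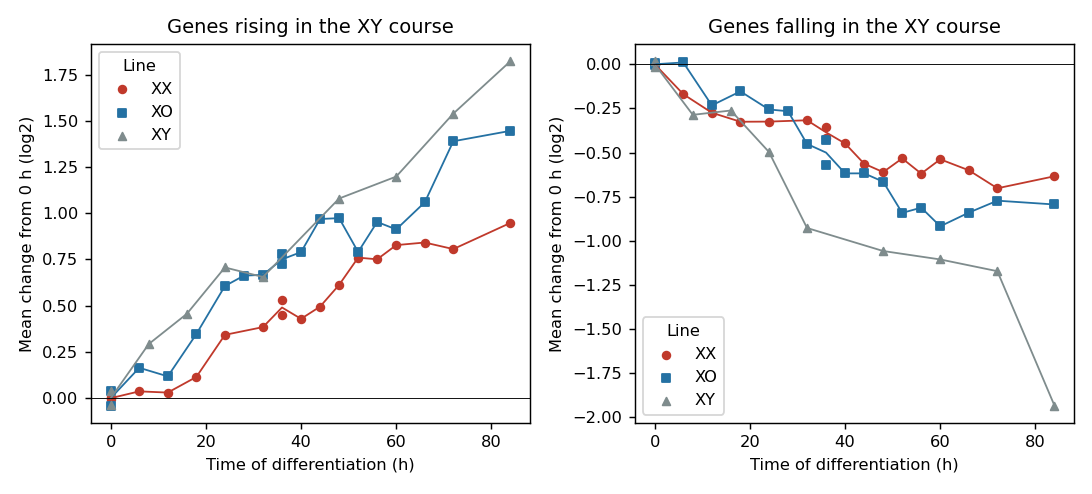
Mean change from 0 h (vertical axis, log2) of the 1952 XY-rising genes (left) and the 2004 XY-falling genes (right) against time of differentiation in hours; each point is an array and lines join the means of each time in XX, XO and XY. For the rising genes XX ends at 0.95, XO at 1.45 and XY at 1.82, and for the falling genes the 84 h values are -0.63, -0.79 and -1.93.

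Placing whole arrays on the XY course summarised the same 3956 genes in hours. XX arrays lay behind XO arrays of the same time at 14 of 15 times and level with them at 12 h. The mean XX minus XO position was -11.9 ± 9.17 h (SD over 15 times; exact sign-flip permutation test, p = 1.22e-04). The difference was -1 h at 6 h, -12 h at 24 h, between -5 and -3 h at 32, 36 and 40 h, and between -21 and -19 h from 44 to 60 h. It was -7 h at 66 h, -24 h at 72 h and -21 h at 84 h. At 84 h the XX array matched XY at 48 h and the XO array matched XY at 69 h. The genes were chosen for their change in XY, so both lines can lie behind XY through that choice alone. Positions moved in jumps. XO went from 31 h at 40 h to 49 h at 44 h, and XX from 30 h at 60 h to 46 h at 66 h. The size of a difference in hours therefore depends on where these jumps fall, on a course fitted to 10 XY arrays.

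**Figure D4:**
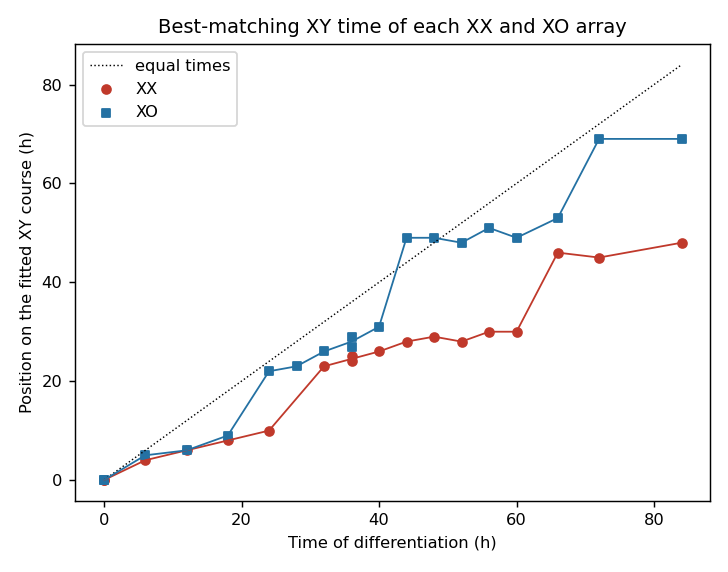
Best-matching hour on the fitted XY course (vertical axis) of each XX and XO array against its own time of differentiation in hours (horizontal axis); lines join the means of each time and the dotted line marks equal times. XX arrays lie at or behind XO arrays at the 15 times after 0 h, with 48 h against 69 h at the end.

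A direct test of XX against XO courses, gene by gene, called 6162 genes whose change with time differed (limma F test), with a higher XX minus XO value for 2520 and a lower value for 3642. Of the 1872 called genes that changed by at least 1 log2 unit in XO, 1213 moved in the same direction by less in XX (64.8%), 223 by more and 436 in the opposite direction. Of the 1200 that changed by as much in XX, 536 moved by less in XO (44.7%), 475 by more and 189 in the opposite direction. Genes chosen for a large change in 1 line tend to change less in the other, so both shares are given. They were 62.0% and 48.2% after centring. The test called 2941 genes with a higher and 3071 with a lower value after centring, and 2836 and 2691 after quantile normalization, so the excess of lower values rests on the scaling. Averaged over the 16 shared times, 4857 genes were higher and 3697 lower in XX (limma, 8554 genes), and 4219 and 4768 after centring or 4248 and 4858 after quantile normalization. By at least 1 log2 unit, 453 were higher and 119 lower on average.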

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

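Tests of the handling of the replicate B samples and of slower passage along 1 course were chosen after the result they bear on had been seen. A difference between groups stood out in 2 results: the change from 0 to 36 h differed between XX and XO for 376 genes, and the whole course differed for 6162 genes. A signal outside the comparisons also stood out, since the reference RNA array lay at least 3 log2 units above every cell array for 130 genes and at least 3 below for 73, with a correlation across genes of 0.844 to the mean of the cell arrays. With 1 reference array this has no replicate check.

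Chance order of the arrays is unlikely to give the full counts of the courses: 1 of 100 orders, the real one, called as many genes in each line. The real and highest other counts were 7745 and 1347 in XX, 12266 and 3144 in XO, and 11420 and 9792 in XY. For XX and XO labels exchanged within times, with the XO 28 h array left out, 1 of 100 splits, the real one, called as many genes. The interaction gave 5626 against at most 5139, and the average difference 8466 against at most 4350. For the XY course and the interaction the highest other counts lie near the real ones. Single genes of those lists can thus also be called with scrambled labels.

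More genes were higher than lower in XX at 0 h, with 1713 of 2082 above XO. Scaling of the arrays argues for part of this but against being the whole cause, since 67.6% of the called genes were still higher in XX after each array was centred on its median, against 82.3% before. Whether the excess is lost during differentiation stays open. The genes chosen on replicate A kept 31.2% of their replicate B difference at 66 to 84 h, and 46.9% of their 6 to 24 h value. They were chosen at 0 h, which alone can make later differences smaller, and no set chosen at a late time was run. Among all genes, 846 were higher and 199 lower in XX by at least 1 log2 unit at 0 h. These numbers were 1840 and 481 at 60 h, 701 and 1024 at 72 h, and 791 and 742 at 84 h, with 1 array per line at these later times. Genes chosen as lower in XX had a median of -0.28 at 0 h and 0.0032 at 66 to 84 h, but their relation to time rests largely on the 2 farthest times, so whether the loss is specific to genes higher in XX stays open. Dosage of the X chromosome, for which undifferentiated XX cells have both copies active, stays open and untested because chromosomes are not known here.

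XX arrays lay behind XO arrays on the XY course, by a mean of -11.9 h. The tables argue against array scaling as the cause, since quantile normalization gave -13.5 h (exact sign-flip permutation p = 1.83e-04). Centred arrays gave -11.97 h (exact sign-flip permutation p = 1.22e-04). Centring shifts all genes of an array alike, and 1952 rising and 2004 falling genes nearly offset such a shift. It could therefore hardly move the position. The tables also argue against genes that already differed at 0 h, since 1626 genes without such a difference gave -12.8 h. Handling of the replicate B samples alone cannot be told apart. The replicate A pair gave -4 h at 36 h, as did the B pair on its own 0 h arrays. Replicate A has no arrays at 44 to 60 h, where the XX minus XO position was -21 to -19 h. XX and XO are 1 line each, so sex chromosome complement, clone and culture history are confounded.

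At 84 h the XX array remained apart from the XO course. Its nearest XO array, at 48 h, lay at a root mean square distance of 0.67 log2 units over 11420 genes, 2.12 times the distance between replicates at 36 h. A bound of 2 against slower passage along the same course was too low, because replicates share their 0 h arrays and XX and XO do not; allowing for the noise of the 0 h means lowers the ratio to 1.73. XX at 6 h already lay at 1.64 times the replicate distance from its nearest XO array. Slower passage and a separate course cannot be told apart with 1 array at 84 h.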

How the results depend on the processing

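Centring, quantile normalization, the gene classes, their alternatives and the removal of the XY 84 h array were chosen after seeing the data. For 15 results, 128 alternatives other than leaving out an array were run: 107 stayed within 1.5 times the count or, for class and position values, kept their direction and side of the threshold, 18 counts moved further, 3 class values lost the threshold, and 0 values of the XY-rising class, the XY-falling class and the position changed sign. Smaller classes changed sign with the scaling: XY-falling before 24 h and both XY transient classes. The excess of higher over lower genes is less stable: it turned in 10 of 24 scaling alternatives (6 with centring, 4 with quantile normalization) and in 5 others, those for 0 to 36 h in XX and the XY course, whose splits were near even. Requiring 1 log2 unit, which removes genes by construction, left 896, 1174 and 841 genes for XX against XO, XX against XY and XO against XY at 0 h, 946 for XX against XO at 36 h, 1542 and 1921 for 0 to 36 h in XX and XO, 2037, 3286 and 3956 for the XX, XO and XY courses, 2865 for the interaction and 572 for the average difference. Genes with a mean above the median (6.95) numbered 2010 for 0 to 36 h in XX, 203 for the difference of the changes and 7608 for the XY course, with fewer genes tested. The spread from all 47 arrays, with fitted values, gave 5797 for XX against XO at 36 h, 5089 and 6844 for 0 to 36 h in XX and XO, and 1947 for their difference; the cause was not tested. The XY-falling difference was 0.075 scaled to each gene's SD (exact permutation p = 0.203) and 0.095 without the XY 84 h array (exact permutation p = 0.0804). It was larger in level, at 0.25 (exact permutation p = 1.22e-04), and over genes with a mean above the median, at 0.15 (exact permutation p = 0.0196). The XY-rising difference in level was -0.087. The cause of these changes was not tested.

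Leaving out each array in turn, with the lone array assumed to vary like the others, gave 689 to 1365 genes for XX against XO at 0 h, 1319 to 2005 for XX against XY, 535 to 758 for XO against XY, 801 to 1065 for XX against XO at 36 h, 1612 to 2907 and 2217 to 2797 for 0 to 36 h in XX and XO, and 57 to 294 for their difference. The courses gave 6806 to 7752 in XX, 11352 to 12377 in XO and 8825 to 11948 in XY. The excess of higher over lower genes turned for 2 of 4 arrays left out for 0 to 36 h in XX, 1 of 18 in the XX course (XX 84 h) and 1 of 10 in the XY course (XY 84 h), and for 0 in the other count results. The XY-falling difference ranged from 0.074 to 0.11, and 18 of 37 arrays left out ended its unadjusted call (highest exact permutation p = 0.0803). The XY-rising difference stayed between -0.31 and -0.23 and the position between -13.2 and -10.7 h, with exact permutation p of at most 2.44e-04.

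A replicate block gave 1837 genes for XX against XO at 0 h and 275 for the difference of the 0 to 36 h changes, and no count moved by over 1.5 times. Deviations of arrays with the same letter correlated at -0.134 to 0.189, above 0.1 for 2 of 10 pairs of conditions. The highest value was between XO and XX at 36 h. These low values give little sign that the letters pair the samples, but they cannot exclude shared handling. The X-linked comparisons, the naive and primed scores, the gene list tests and autosomal centring were not run. With 2 arrays per condition, a change of 1 log2 unit at 0 h was recovered in 30% of 100 simulated genes; the simulation held fewer changed genes than the data, which makes its adjusted threshold stricter.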

Other observations

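Genes that moved in XY and came back by 84 h were described in none of the comparisons. The XY transient rise held 406 genes, whose mean change at 24 h was 0.58 in XX, 0.80 in XO and 0.89 in XY and at 84 h was 0.34, 0.38 and 0.11. Their XX minus XO difference was -0.049 (exact sign-flip permutation test, adjusted p = 0.265), with XX higher at 4 of 15 times; it was 0.026 after centring and 0.00998 after quantile normalization, so its sign depends on the scaling. The XY transient fall held 356 genes, with changes at 48 h of -0.53 in XX, -0.42 in XO and -0.91 in XY. Their XX minus XO difference of -0.098 passed (exact sign-flip permutation test, adjusted p = 0.0190), but it was -0.023 after centring and 0.0026 after quantile normalization (same permutation test, adjusted p = 0.361 and 0.911), so it rests on the scaling. These classes were chosen after seeing the data.

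The nearest XO time to each XX time moved little over the second part of the course. XX at 44, 48, 52, 56, 60 and 66 h was nearest to XO at 36 h. XX at 24, 32, 36 and 40 h was nearest to XO at 18 h, and XX at 72 and 84 h to XO at 40 and 48 h. Replicates were averaged, so XO at 36 h was a mean of 2 arrays, while the other XO times after 0 h had 1. Averaging lowers noise and with it the distance, which favours 36 h as the match. The distance rose from 0.46 log2 units at 24 h to 0.67 at 84 h.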
